A study of Mus musculus with 4 samples.

How the data were processed

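Total RNA labelled as coming from 4 cultures of the mouse mast cell line MC/9 was measured on Affymetrix Mouse Genome 430 2.0 arrays, 1-colour arrays on which a transcript is read by probe sets of short oligonucleotides. The groups were untreated cells (control), cells given berberine at 10 microM (BER), cells given an anti-DNP IgE antibody at 500 microg/ml (labelled DNP) and cells given both (BER+DNP). For BER, DNP and BER+DNP the labels give 24 h of treatment followed by 6 h of culture. They give no times for the control, so whether it was cultured for as long is not known. Each group holds 1 array, so no value has a replicate error and no p-value is given anywhere. The number of arrays limits the precision.

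The deposited table holds log2 signals of 45101 probe sets on the 4 arrays. Per the submitters' processing notes, the authors made it with Affymetrix Expression Console; the version, the summary algorithm, the background correction and the detection calls are not given in the sources used here. That the scale is log2 was read from the values, which run from about 1 to 14. The medians of the 4 arrays lay at 3.13 for control, 3.15 for BER, 3.14 for DNP and 3.14 for BER+DNP, so the table was taken as already normalized between arrays and was used as deposited. Any floor or smoothing that the unstated algorithm applied at low signals stays in the values and can shrink the differences of dim genes.

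The 64 control probe sets were set apart, which left 45037. Gene symbols came from an annotation of the platform dated 2016. It gave 1 symbol to 34945 probe sets, several to 932 and none to 9160, and no gene was named from a probe set with several. Of the probe sets with 1 symbol, 34741 matched a gene of the RefSeq annotation of mouse assembly GRCm38.p6 by gene identifier, and 0 symbols had to be updated. That annotation served for names only, and no coordinates are given because the array table names no genome build. A gene was represented by its brightest probe set, by mean log2 signal over the 4 arrays, which gave 18193 genes. Genes entered counts and lists if that mean was at or above the median of all non-control probe sets, 3.138, which left 12585.

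The comparisons were BER against control, DNP against control, BER+DNP against DNP, BER+DNP against control and BER+DNP against BER, each a difference of log2 signals between 2 arrays. The difference of the BER differences is (BER+DNP minus DNP) minus (BER minus control). Genes at least 2-fold apart were counted in each comparison. The 2 BER pairs (BER with control, BER+DNP with DNP) share no array, nor do the 2 DNP pairs (DNP with control, BER+DNP with BER), and agreement between such pairs was the only check on repeatability: genes at least 1.5-fold apart in the same direction in both pairs were counted, and the differences were correlated across genes. An additive model, which would leave 1 residual degree of freedom, was not fitted. Counts for the 2 berberine pairs are set beside 1000 simulated sets of 4 arrays with no effect. The noise of these sets was drawn from the observed differences of differences in 20 bins of expression, so counts of that difference are not judged against it. For those counts the simulated sets gave a median of 5 genes in each direction, where 12 were observed. The simulated noise may therefore hold too few large differences. Correlations between comparisons that share an array are set beside 100 such simulations.

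For gene lists, the median log2 difference of the measured members was placed among 10000 random lists of the same size matched on mean expression. The percentile describes these arrays and is not a p-value, and genes of a list are not independent. The 34 lists, holding 722 entries, were written before the data were examined, as were the comparisons, thresholds, filter, alternatives and the rule for naming genes. A further 2 lists, of genes that nearly all blood cells use and of epithelial genes, were written after the signals had been seen. The rule names, for BER and for DNP, up to 8 higher and 8 lower genes by mean difference among those at least 1.5-fold apart in both pairs. It adds the 8 highest and 8 lowest genes of BER+DNP against DNP, the 6 highest and 6 lowest of the difference of differences and the 5 highest and 5 lowest of BER+DNP against control. It also takes 18 measured genes of mast cell activation fixed in advance, and up to 4 members with the largest differences in each list described. Symbols of unannotated transcripts were passed over. Genes outside this rule are named as such.

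The steps were tested on simulated arrays with known changes and normal noise, whose SD per expression bin gave little weight to large differences. For BER in both pairs of arrays, over 12585 genes, 98 of 100 genes changed 2-fold and 21 of 100 genes changed 1.5-fold were found by the 1.5-fold rule, and 0 unchanged genes were called. Normal noise of this kind gave a median of 1 gene higher by 2-fold in the difference of differences, where 12 were observed. The 0 false calls therefore do not carry over to the real arrays. The alternatives were quantile normalization, cyclic loess, no filter, a filter at the 75th percentile (4.314), 32 or 100 added on the linear scale, the median of all probe sets of a gene, leaving out probe sets whose type can cross-hybridise (suffixes x and s), and the other fold threshold. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, cyclic loess used limma 3.58.1 in R 4.3.3, and figures used matplotlib 3.10.9. Probe sequences and scanner images were not used here.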

Results

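The arrays measured transcripts in RNA labelled as coming from MC/9 cells, a growth factor-dependent mast cell line from mouse fetal liver. Mast cells carry IgE on the receptor FceRI and release histamine, proteases and cytokines when that IgE is crosslinked. Berberine is a plant alkaloid that inhibits mitochondrial complex I. The series asks which genes take part in an anti-inflammatory action of berberine in cells given anti-DNP IgE, an antibody against the hapten dinitrophenyl; the labels name no antigen step. The 4 groups (control, BER, DNP and BER+DNP) held 1 array each, so the differences below have no replicate check. The arrays were close to each other, with Pearson correlations across 45037 probe sets between 0.988 and 0.991.

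Probe sets of several genes that define mast cells were dim on all 4 arrays. Cpa3, the mast cell carboxypeptidase, had log2 signals of 1.90 in control, 3.15 in BER, 2.55 in DNP and 2.51 in BER+DNP, against an array median near 3.13. Kit, the stem cell factor receptor, lay between 2.60 and 3.01, Fcer1a, the IgE-binding chain of FceRI, between 2.31 and 2.58, and Ms4a2, its beta chain, between 2.54 and 2.85. Fcer1g, the signalling chain, reached 3.76 at most and Il6 1.75, while the histamine-forming enzyme Hdc lay between 5.32 and 5.86, at the 84.4th percentile of genes, and Tnf between 4.95 and 5.05. The median granule gene stood at the 38.9th percentile and the median mast cell identity gene at the 45.7th. FceRI signalling genes stood at the 63.6th percentile, cytokines and chemokines at the 42.3rd, housekeeping genes at the 70.0th. Genes used by nearly all blood cells, in a list written after the signals were seen, stood at the 44.2nd percentile, with Ptprc, the common leukocyte antigen, at a mean of 2.29. Epithelial genes, also listed afterwards, stood at the 75.1st, led by the keratin gene Krt17 at 9.60. These ranks compare signals of different probe sets and are not levels of expression: in 4741 genes above the 75th percentile with several probe sets, the 2 brightest of a gene lay a median of 1.62 log2 apart, and over 4-fold apart in 39.5% of genes. Differences in mast cell genes therefore rest mostly on weak signals.

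**Figure D1:**
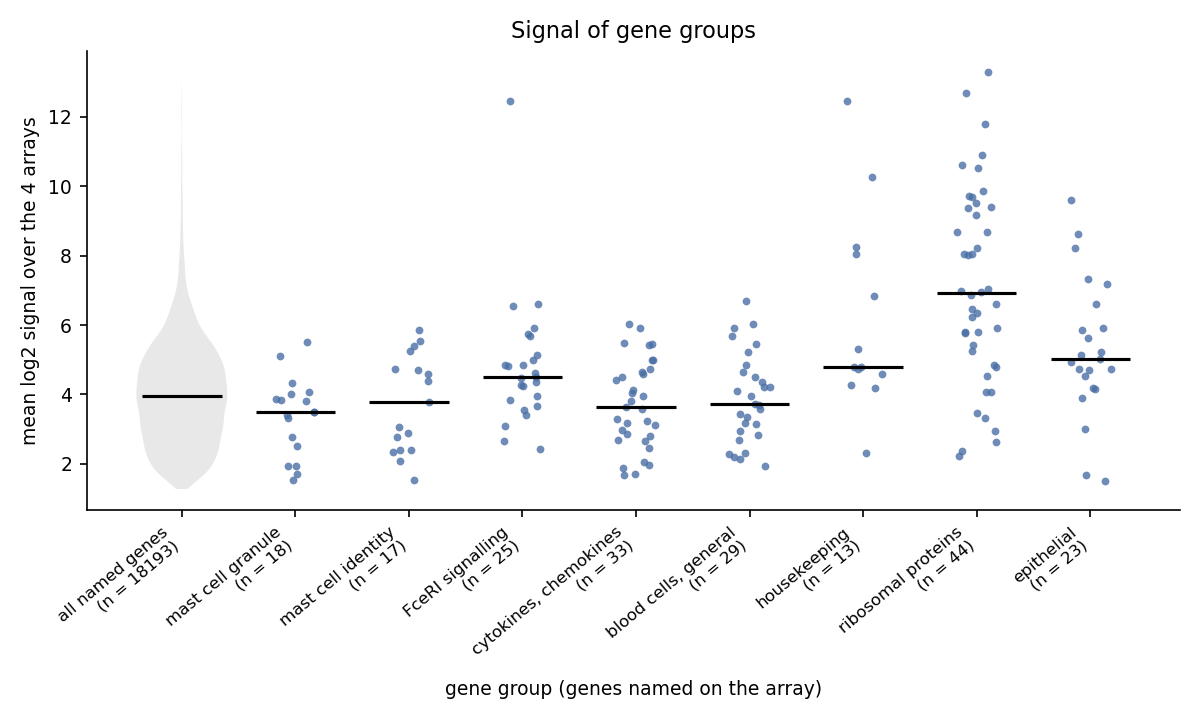
Mean log2 signal over the 4 arrays (vertical axis) of the genes in 8 groups, 1 point per gene, beside the distribution of all 18193 named genes; black bars are medians. The median granule gene lies below that of all named genes, and the 44 ribosomal protein genes spread widely around a median at the 96.1st percentile of genes, with 6 of them below the median gene.

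Berberine alone against control asked what the compound does in otherwise untreated cells. Of 12585 genes, 8 were at least 2-fold higher and 4 at least 2-fold lower. Ufsp1, a protease that matures the protein modifier UFM1, was 2.31-fold higher, the kinase gene Cdkl4 2.27-fold, Asns, which makes asparagine, 2.17-fold, the lipase gene Abhd4 2.10-fold, N6amt1, a methyltransferase gene, 2.06-fold and Btg1, which restrains cell division, 2.04-fold. The other genes past 2-fold were B3gnt8 and Cntd1, higher by 2.19-fold and 2.04-fold. The ribosomal protein gene Rps29 was 2.70-fold lower and Gja1, a gap junction connexin gene, 2.17-fold lower; Gjc1, another connexin gene, and Ivns1abp were lower by 2.15-fold and 2.01-fold and were named after their values were seen. Simulated arrays with no effect gave a median of 0 genes and rarely more than 1 in each direction. Their noise may hold too few large differences, so this does not settle whether the counts exceed noise. For N6amt1, Cdkl4 and Cntd1 the control signal (3.02, 3.01 and 2.54), and for Gjc1 and Ivns1abp the BER signal (3.07 and 3.11), lay below the filter of 3.138, so these folds are approximate. The counts were 2 and 0 with the median of all probe sets, 3 and 2 with the filter at the 75th percentile and 1 and 2 with 32 added to the signals; at 1.5-fold they were 127 higher and 124 lower.

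Berberine in the presence of anti-DNP IgE (BER+DNP against DNP) addressed the stated purpose most directly. Past 2-fold were 1 higher gene, Cdkl4 (2.77-fold), and 1 lower gene, Rps29 (2.33-fold), which is no more than simulated arrays with no effect reach. Next in order among higher genes came Ufsp1 (log2 difference 0.87), Btg1 (0.83), Rbsn, an endosomal Rab effector gene (0.82), Ypel5 (0.81), the dopamine receptor gene Drd2 (0.79), Mars1, which charges methionine tRNA (0.77), and the helicase gene Dhx9 (0.77). Next among lower genes came Rnf121 (-0.95), Rrp36 (-0.94), Dmac2 (-0.92), Gsg1l (-0.91), the mitochondrial carrier gene Slc25a11 (-0.87), Adam8, a membrane protease gene (-0.87), and Timm10b, of the mitochondrial import machinery (-0.86). Drd2 and Cdkl4 in DNP, and Rrp36 and Gsg1l in BER+DNP, read below the filter. Rbsn had a difference of -0.10 when all its probe sets were taken by their median. At 1.5-fold, 64 genes were higher and 88 lower.

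The 2 berberine pairs share no array, and 30 genes lay at least 1.5-fold apart in the same direction in both: 10 higher and 20 lower. Independent lists of those sizes would share 0.646 and 0.867 genes, and simulated arrays with no effect, whose noise may hold too few large differences, rarely more than 1. The lower genes numbered 12 with quantile normalization and 13 without probe sets that can cross-hybridise; the counts were 5 and 9 with the median of all probe sets, 3 and 8 with 32 added to the signals and 2 and 4 with 100 added. In the main analysis, 0 genes lay 1.5-fold apart in opposite directions. Higher in both pairs were Cdkl4 (log2 differences 1.18 without and 1.47 with anti-DNP IgE), Ufsp1 (1.21 and 0.87), Btg1 (1.03 and 0.83), Asns (1.12 and 0.73), Abhd4 (1.07 and 0.69), N6amt1 (1.04 and 0.65), Ypel5 (0.80 and 0.81) and Fads3, of the fatty acid desaturase family (0.88 and 0.64). Lower in both were Rps29 (-1.43 and -1.22), Gja1 (-1.12 and -0.81), Prelid1, a mitochondrial lipid transfer gene (-0.77 and -0.81), Mycbp, which encodes a MYC-binding protein (-0.88 and -0.69), Filip1l (-0.79 and -0.72), Sat1, of polyamine breakdown (-0.91 and -0.59), Timm17a, of the mitochondrial inner membrane translocase (-0.66 and -0.81), and Atp1b1, a sodium pump subunit gene (-0.69 and -0.76). The differences of all genes correlated between the pairs at r = 0.231 (Spearman's rho 0.197), where simulated arrays gave r between -0.0186 and 0.0170. From the dimmest to the brightest of 4 equal parts of the genes, r was 0.126, 0.118, 0.189 and 0.495, and with 32 or 100 added to the signals of all genes 0.378 or 0.502. These correlations are across genes, which are not independent replicates. The simulated noise was drawn for each gene separately, so it holds no difference shared by many genes of an array, such as one of RNA quality. The simulated range near 0 therefore does not show that r reflects berberine.

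Other probe sets of these genes gave mixed results. Over 4089 pairs of probe sets of the same gene, the differences of the 2 correlated at only r = 0.074 in BER against control and 0.096 in BER+DNP against DNP. Of the 30 genes, 20 had a further probe set past the filter, 35 probe sets in all, and 23 of the 35 went the same way in both pairs, 3 of them by at least 1.5-fold. Cdkl4 read 3.01 in control and 3.12 in DNP, below the filter of 3.138, and its other probe set, dimmer still, gave 0.22 and -0.27. Timm17a read 2.77 in BER and 2.99 in BER+DNP, also below it. A second probe set of Btg1 gave 1.03 and 0.79, and those of Gja1 with signals near 10.0 and 8.9 gave -0.80 and -0.81, and -1.06 and -0.79. The bright Gja1 probe sets all carry the suffix x, of the type that can cross-hybridise. Of 2 dimmer ones past the filter, another with suffix x gave -0.56 and -0.59, and one without it -0.17 and -0.02. Other probe sets of Atp1b1 gave -0.44 and -0.62, -0.10 and -0.28, 0.03 and -0.10, and 0.06 and 0.10. Those of Prelid1 gave -0.18 and -0.08, and -0.28 and -0.17. A second Rps29 probe set of similar brightness gave only -0.09 and -0.19, and a second Abhd4 probe set 0.17 and 0.27. Without probe sets that can cross-hybridise, Ufsp1 was read by a probe set below the filter, with -0.09 in BER against control and 0.38 in BER+DNP against DNP, and for Fads3 the median of all probe sets gave -0.06 in BER+DNP against DNP.

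**Figure D2:**
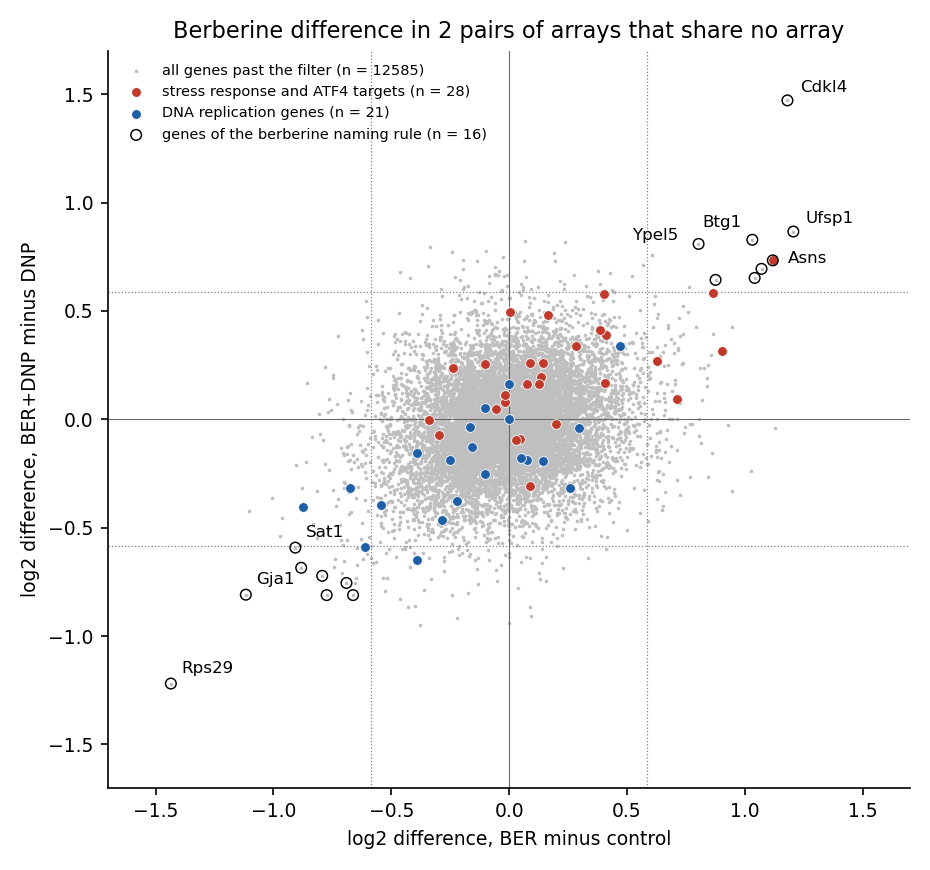
Log2 difference of each of 12585 genes between BER and control (horizontal axis) and between BER+DNP and DNP (vertical axis); dotted lines mark 1.5-fold. Red points are the 28 measured stress response and ATF4 target genes, blue points the 21 DNA replication genes, and open circles the 16 genes named by the rule for berberine. Cdkl4 and Rps29 lie farthest out in opposite corners, and r over all genes is 0.231.

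Among the 34 gene lists, 2 lay outside the middle 95% of random lists in both berberine pairs, where independent pairs would give 0.0425 on the same side. Targets of ATF4, the transcription factor of the integrated stress response, were higher, with medians of 0.13 (99.9th percentile) without and 0.22 (above all 10000 random lists) with anti-DNP IgE; 17 of the 28 measured members lay above 0 in both pairs and 2 below 0 in both, against 25.4% and 29.7% of all genes. The largest members were Asns, Vldlr, a lipoprotein receptor gene (0.90 and 0.31), the transcription factor gene Cebpb (0.87 and 0.58) and the alanyl-tRNA synthetase gene Aars (0.71 and 0.09), with Gars, which charges glycine tRNA, at 0.40 and 0.58 and Ddit3, which encodes CHOP, at 0.01 and 0.50. Only Asns passed 1.5-fold in both pairs. DNA replication genes were lower, with medians of -0.16 (0.35th percentile) and -0.19 (0.17th); 12 of 21 lay below 0 in both pairs and 1 above. Rrm2, a ribonucleotide reductase subunit gene, gave -0.87 and -0.41, the clamp loader gene Rfc3 -0.67 and -0.32, the sliding clamp gene Pcna -0.61 and -0.59, the helicase gene Mcm7 -0.54 and -0.40 and Gins2 -0.39 and -0.65. Mitosis genes had medians of -0.01 and -0.01. Poly-A control transcripts, added during sample preparation, were lower by a median of -0.48 in BER against control and -0.14 in BER+DNP against DNP, while hybridisation controls gave 0.03 and 0.10. Control probe sets for beta-actin were lower with berberine, more so at the 5' end (-0.57 and -0.59) than at the 3' end (-0.31 and -0.22); those for Gapdh were flat, with 0.05 and -0.08 at the 5' end and -0.03 and 0.02 at the 3' end. ATF4 targets had 0.13 in BER+DNP against DNP with the median of all probe sets, and DNA replication genes -0.10 in BER against control without the filter and -0.32 in BER+DNP against DNP with the filter at the 75th percentile. With 32 added to the signals the medians were 0.07 and 0.11 for ATF4 targets and -0.08 and -0.08 for DNA replication genes.

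Several other lists lay below 0 in both berberine pairs, mostly inside the middle 95%. Complex I subunit genes had medians of -0.08 (9.93th percentile) and -0.14 (1.37th), with 14 of 24 below 0 in both pairs; Ndufs8 gave -0.43 and -0.29 and Ndufv1 -0.46 and -0.22. Ribosome biogenesis genes had -0.10 (7.42th) and -0.16 (2.16th), led by the nucleolar gene Nop56 at -0.75 and -0.32. Unfolded protein response genes of the endoplasmic reticulum had -0.10 and -0.13, with the secreted factor gene Manf at -0.80 and 0.02 and the chaperone gene Hsp90b1 at -0.29 and -0.49. Heat shock genes had -0.09 and -0.11, with Hspa8 at -0.50 and -0.46 and the co-chaperone gene Ahsa1 at -0.62 and -0.22. That list was written as cytosolic but also holds the mitochondrial chaperone genes Hspa9 and Hspe1. Lysosome genes had -0.11 and -0.07, glycolysis genes -0.12 and -0.05 and type I interferon response genes -0.02 and -0.05. Near 0 lay cholesterol synthesis genes (0.02 and -0.04), fatty acid synthesis genes (0.01 and 0.01), hypoxia response genes (0.00 and 0.02) and housekeeping genes (-0.02 and -0.07). NRF2 targets had 0.06 and 0.05, p53 targets 0.09 and 0.03 and aryl hydrocarbon receptor targets 0.05 and 0.10, all inside the middle 95%.

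**Figure D3:**
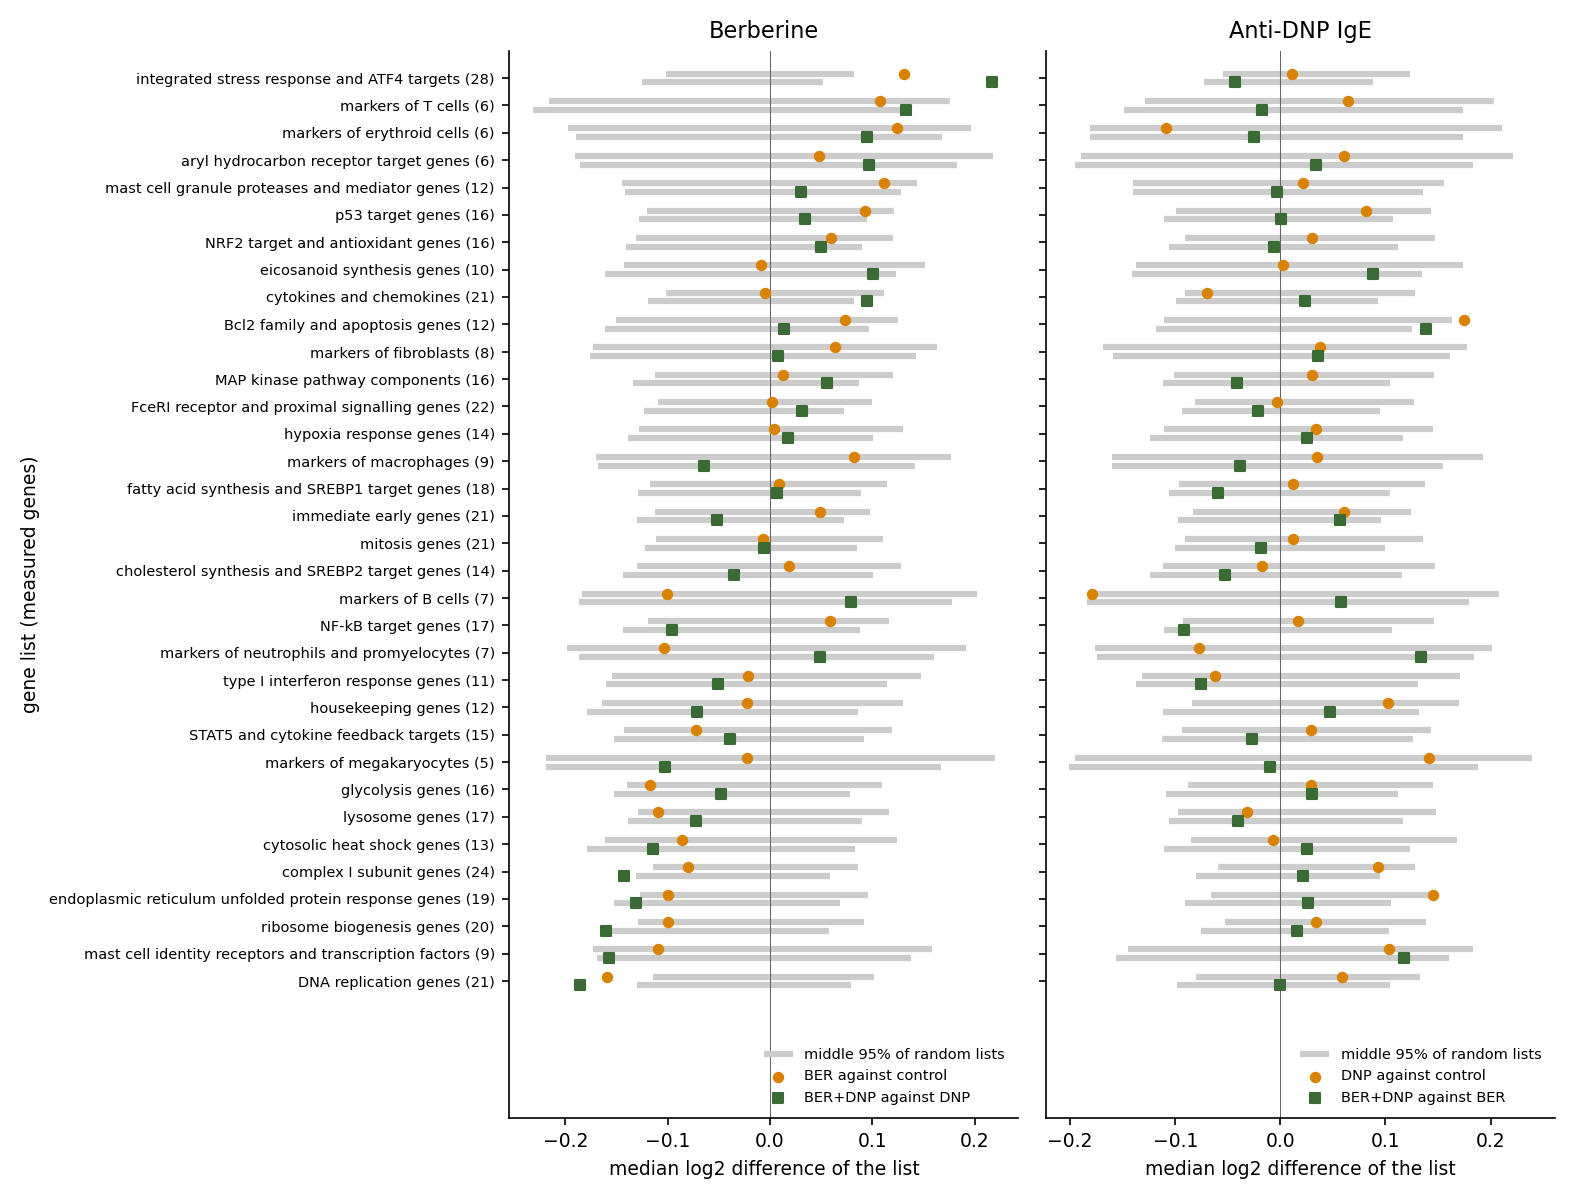
Median log2 difference (horizontal axes) of the 34 gene lists, with the number of measured genes in parentheses, for the berberine pairs (left) and the anti-DNP IgE pairs (right); circles and squares are the 2 pairs, and grey bars the middle 95% of 10000 matched random lists. The ATF4 targets lie right of both bars at 0.13 and 0.22 and the DNA replication genes left of both at -0.16 and -0.19.

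In the groups tied to mast cell activation, berberine gave small differences. Cytokines and chemokines had medians of -0.01 (41.0th percentile) without and 0.10 (98.6th) with anti-DNP IgE. Among their members, Tgfb1 gave -0.33 and -0.74 and Lif -0.51 and -0.27, while Il5 gave -0.14 and 0.31 and the chemokine gene Ccl17 0.08 and 0.29. Tnf (0.04 and 0.04), Ccl2 (0.00 and 0.00), Ccl3 (0.02 and -0.02) and Csf2 (0.17 and 0.09) differed little. Of these, Ccl3 and Csf2 read close to the filter, with mean log2 signals of 3.245 and 3.305, and Ccl2 was dim at 3.643. Detection calls are not given, so small differences in Ccl2, Ccl3 and Csf2 do not show that berberine left them unchanged. Il4 (0.43 and -0.26), Il6 (-0.04 and 0.07) and Il13 (-0.15 and -0.11) were below the filter. Granule genes had medians of 0.11 and 0.03, with Hdc at -0.14 and 0.50. FceRI signalling genes had 0.00 and 0.03, with Fcer1g at -0.42 and -0.08, and mast cell identity genes -0.11 and -0.16, with the transcription factor gene Spi1 at -0.41 and -0.41. NF-kB targets had 0.06 and -0.10, MAP kinase pathway genes 0.01 and 0.06, STAT5 and cytokine feedback targets -0.07 and -0.04, and eicosanoid synthesis genes -0.01 and 0.10; in NF-kB targets Tnfaip3, which dampens the pathway, gave -0.53 and 0.02 and Traf1 -0.06 and -0.46.

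Anti-DNP IgE alone against control asked what the antibody does without berberine. No gene was 2-fold apart: 0 were higher and 0 lower, the largest differences being 0.99 and -0.95, and 101 and 79 genes passed 1.5-fold. Without the filter 1 gene was 2-fold higher and 3 lower. In both anti-DNP IgE pairs, 2 genes were at least 1.5-fold higher, the transcription factor gene Sp1 (0.59 without and 0.81 with berberine) and Sh2b3, which encodes an adaptor that restrains cytokine signalling (0.62 and 0.59). The 2 lower genes were Akp3, an alkaline phosphatase gene (-0.72 and -0.65), and Ager, which encodes the receptor for advanced glycation end products (-0.67 and -0.62). Independent lists would share 0.562 and 0.283 genes. Of the 4 genes, Sh2b3 and Ager each had 1 other probe set past the filter, and 0 of these 2 went the same way in both pairs. The median of all probe sets gave -0.47 for Sp1 in DNP against control, and without probe sets that can cross-hybridise Ager gave 0.14 there. That Sp1 median was the reading of a single probe set below the filter, 2.54 in control and 2.07 in DNP. Across genes the pairs correlated at r = 0.173 (rho 0.174).

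Genes of mast cell activation showed little with anti-DNP IgE in their medians, which all lay inside the middle 95%. Immediate early genes, which respond first to receptor signalling, had medians of 0.06 without and 0.06 with berberine, 11 of 21 genes above 0 in both pairs and 3 below, with Fos at 0.71 and 0.26 and the mRNA decay gene Zfp36 at 0.53 and 0.09. The treated cells were read after 24 h of treatment and 6 h of culture, so these values do not show whether an early response occurred. The IgE receptor genes Fcer1a and Ms4a2 had mean log2 signals of 2.43 and 2.67, below the filter, and the labels name no antigen step. Small medians therefore do not show that mast cells able to respond had failed to do so. Cytokines and chemokines had -0.07 and 0.02, with 18 of 21 genes below 0 in DNP against control, 2 above 0 in both pairs and 8 below 0 in both, and with Ccl1 at -0.58 and -0.35 and Cxcl1 at -0.51 and -0.17. Granule genes had 0.02 and 0.00, with the chymase-family genes Mcpt2 at 0.68 and 0.31 and Mcpt4 at 0.60 and 0.02. NF-kB targets had 0.02 and -0.09 and FceRI signalling genes 0.00 and -0.02. Ptgs2, a prostaglandin synthase gene, gave 0.48 below the filter, Alox5, of leukotriene synthesis, 0.08, Ccl4 -0.20, Tpsb2, a tryptase gene, 0.11 and Cma1, a chymase gene, 0.34. Bcl2 family and apoptosis genes were the list outside the middle 95% in both pairs, with medians of 0.17 (98.3rd percentile) and 0.14 (98.6th); 7 of 12 lay above 0 in both and 0 below. Members included Bcl2, which protects from apoptosis, at 0.52 and 0.16, and Diablo, which promotes it, at 0.38 and -0.07. In BER+DNP against BER the difference of that list was lost with the median of all probe sets (-0.002) and without the filter (0.002). Unfolded protein response genes had 0.14 (97.7th percentile) and 0.03, with Pdia6, a protein disulfide isomerase gene, at 0.46 and 0.12.

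Cells given both agents were also set against control and against BER. Against control, 4 genes were at least 2-fold higher, namely Cdkl4 (2.99-fold), Wnt8b, a secreted signalling protein gene (2.15-fold), Btg1 (2.15-fold) and Pgr, the progesterone receptor gene (2.08-fold), followed by Tsc22d1 at a log2 difference of 1.00. The 5 lower genes were Rps29 (2.64-fold), Ammecr1l (2.21-fold), Cdx2, a homeobox gene (2.03-fold), Alkbh3os1 (2.02-fold) and the nuclear export gene Xpo4 (2.00-fold). Pgr and Tsc22d1 in control and Alkbh3os1 in BER+DNP read below the filter, and with the median of all probe sets the counts were 1 higher and 2 lower. In that analysis Pgr, which had no other probe set past the filter, gave -0.21 and Tsc22d1 -0.20. Other probe sets past the filter were read in BER against control and in BER+DNP against DNP. Those of Ammecr1l gave 0.27 and 0.16, and -0.02 and -0.05. That of Cdx2 gave 0.23 and 0.10 and that of Xpo4 -0.27 and 0.01, where the named probe sets of these genes lay below 0 in both. That of Wnt8b gave -0.37 and 0.54, that of Rps29 -0.09 and -0.19, and that of Btg1 1.03 and 0.79. ATF4 targets had a median of 0.20 (99.99th percentile), DNA replication genes -0.18 (0.16th), granule genes 0.17 (98.8th), Bcl2 family genes 0.15 (98.2nd), heat shock genes -0.17 (1.56th) and interferon response genes -0.17 (2.14th). The interferon list held 11 measured genes, and its median was 0.00 without the filter and 0.01 without probe sets that can cross-hybridise. Against BER, 0 genes were 2-fold higher and 0 lower, and 70 and 45 passed 1.5-fold.

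The difference of the BER differences asks whether berberine acted differently with anti-DNP IgE present. At 2-fold, 12 genes had a higher and 12 a lower berberine difference with anti-DNP IgE. Each such value carries the noise of 4 arrays, and the simulated noise was itself drawn from these values, so nothing here says whether the counts exceed noise. Zfas1, Drd2, Alas2, Pla2g15 and Cntd1 read below the filter on at least 1 array. Highest were Prkcq, a protein kinase C gene of immune cells (1.15), the noncoding RNA gene Zfas1 (1.14), Drd2 (1.13), Tspan8 (1.11), Mmp23 (1.07) and the erythroid haem synthesis gene Alas2 (1.05). The difference of Tspan8 was lost with the median of all its probe sets, though no other probe set of it passed the filter. Another probe set of Mmp23 past the filter gave 0.14 in BER against control and -0.03 in BER+DNP against DNP, where the named probe set gave -0.60 and 0.47. Lowest were the lysosomal phospholipase gene Pla2g15 (-1.28), Cntd1 (-1.27), B3gnt8 (-1.17), Wars2, a mitochondrial tryptophanyl-tRNA synthetase gene (-1.11), Mxra8 (-1.08) and Dctn6 (-1.06). Another probe set of Wars2 past the filter gave 0.29 and 0.04 in the 2 berberine pairs, where the named probe set gave 0.845 and -0.265. Cytokines and chemokines had a median of 0.18 (99.8th percentile) eicosanoid synthesis genes 0.19 (98.6th) and B cell markers 0.27 (98.7th, with 7 of 7 genes above 0), so lists outside the middle 95% were not only those of mast cell mediators. The SD across genes of this difference, 0.275, was below that of both arrays with berberine minus both without, 0.347, and of the same sum for anti-DNP IgE, 0.327.

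Comparisons that share an array are correlated with no effect at all. BER against control and DNP against control correlated at 0.407, below the 0.502 of simulated arrays, with a covariance of 0.0209 against 0.0189. DNP against control and BER+DNP against DNP correlated at -0.436, against -0.499 in simulated arrays, with a covariance of -0.0204 against -0.0188. Opposite differences of single genes in the last pair can therefore arise from the shared DNP array as well. An example is Adam8, at 0.67 with anti-DNP IgE and -0.87 when berberine was added, for which this was not tested. Markers of other cell types were measured by 5 to 9 genes each. T cell markers had a median of 0.13 (97.9th percentile) in BER+DNP against DNP, and B cell markers -0.18 (2.38th) in DNP against control. Within the middle 95% in BER against control and in BER+DNP against DNP lay markers of macrophages (0.08 and -0.07), neutrophils and promyelocytes (-0.10 and 0.05), erythroid cells (0.12 and 0.10), megakaryocytes (-0.02 and -0.10) and fibroblasts (0.06 and 0.01). Over all 34 lists and 5 comparisons, 18 of 170 medians lay outside the middle 95%, where 8.5 would by chance.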

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

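The control probe set for the 3' end of 18S ribosomal RNA, which no comparison of the report uses, read higher in both arrays with anti-DNP IgE, and this signal outside the main measurement was the reason for a closer look. Its log2 signal was 11.40 in control, 11.36 in BER, 12.56 in DNP and 12.43 in BER+DNP, a difference of 1.16 in DNP against control and 1.03 in BER+DNP against control. BER+DNP against BER, the pair that shares no array with DNP against control, gave 1.08, and BER against control gave -0.05. The probe sets for the 5' end and the middle of 18S ribosomal RNA gave -0.22 and -0.28 in DNP against control but 0.49 and 0.23 in BER+DNP against BER. The difference was not tested, and no cause was examined.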

How the results depend on the processing

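The labels carry no replicate numbers, and each group holds 1 array, so no replicate could be left out. An additive fit, which the 4 arrays allow with 1 residual degree of freedom, was not run. Counts and leading list medians kept 114 of 208 alternative values, while 93 moved and 1 reversed. List medians kept 1182 of 1352, with 167 moved and 3 reversed, and single genes kept 792 of 1010, with 209 moved and 9 reversed. The cause of the differences given below was not tested, except that added signal shrinks every difference and a stricter filter removes genes. The alternatives for the 2 lists added after the data were seen were also chosen then.

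With 1.5-fold in place of 2-fold, higher and lower genes numbered 127 and 124 in BER against control, 101 and 79 in DNP against control, 64 and 88 in BER+DNP against DNP, 114 and 110 in BER+DNP against control, 70 and 45 in BER+DNP against BER, and 248 and 289 for the difference of the BER differences. With 2-fold in place of 1.5-fold, 1 gene was higher and 1 lower in both berberine pairs, and 0 and 0 in both anti-DNP IgE pairs.

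Without the expression filter, DNP against control gave 1 higher and 3 lower genes at 2-fold, 5 genes were lower in both anti-DNP IgE pairs, and 20 had a lower berberine difference with anti-DNP IgE. The median of ATF4 targets in BER+DNP against DNP was 0.163, that of DNA replication genes in BER against control -0.103, those of Bcl2 family and apoptosis genes 0.089 in DNP against control and 0.002 in BER+DNP against BER, and that of type I interferon response genes in BER+DNP against control 0.001. With the filter at the 75th percentile, BER against control gave 3 higher and 2 lower genes, BER+DNP against DNP 0 higher, BER+DNP against control 1 higher, both anti-DNP IgE pairs 1 higher and 1 lower, and the difference of the BER differences 4 and 2. DNA replication genes gave -0.319 in BER+DNP against DNP, and genes used by nearly all blood cells gave 0.073 in DNP against control, the opposite sign.

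With 32 added on the linear scale, 2-fold higher and lower genes numbered 1 and 2 in BER against control, 0 and 0 in BER+DNP against DNP, 1 and 1 in BER+DNP against control, and 0 and 0 for the difference of the BER differences. Both berberine pairs shared 3 higher and 8 lower genes, both anti-DNP IgE pairs 0 and 0, and the correlation of the berberine differences was 0.378. ATF4 targets gave 0.068 in BER against control and 0.110 in BER+DNP against DNP, DNA replication genes -0.076 and -0.080, and Bcl2 family and apoptosis genes 0.065 in DNP against control. With 100 added, the counts were 0 and 1, 0 and 0, 0 and 0, and 0 and 0 in the same order. The berberine pairs shared 2 and 4 genes, the anti-DNP IgE pairs 0 and 0, and the correlation was 0.502. ATF4 targets gave 0.038 and 0.065, DNA replication genes -0.031 and -0.031, and Bcl2 family and apoptosis genes 0.032 in DNP against control and 0.038 in BER+DNP against BER.

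With the median of all probe sets of a gene, 2-fold higher and lower genes numbered 2 and 0 in BER against control, 0 and 0 in BER+DNP against DNP, 1 and 2 in BER+DNP against control, and 7 and 4 for the difference of the BER differences. Both berberine pairs shared 5 higher and 9 lower genes, and both anti-DNP IgE pairs 0 and 1. ATF4 targets gave 0.130 in BER+DNP against DNP and Bcl2 family and apoptosis genes -0.002 in BER+DNP against BER, the opposite sign. Opposite signs also came from Fads3 (-0.056) and Rbsn (-0.099) in BER+DNP against DNP, Pgr (-0.215) and Tsc22d1 (-0.199) in BER+DNP against control, Sp1 (-0.468) in DNP against control, and Tspan8 (-1e-05) for the difference of the BER differences.

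Without probe sets that can cross-hybridise, 2-fold lower genes numbered 2 in BER against control, 0 in BER+DNP against DNP and 3 in BER+DNP against control, while 13 were lower in both berberine pairs and 1 in both anti-DNP IgE pairs. ATF4 targets gave 0.163 in BER+DNP against DNP. Opposite signs came from Ager (0.138 in DNP against control, 0.073 in BER+DNP against BER), Ufsp1 (-0.088 in BER against control) and type I interferon response genes (0.012 in BER+DNP against control). The median log2 difference of integrated stress response and ATF4 targets, BER+DNP against DNP, was 0.262 with quantile normalization and 0.265 with cyclic loess; 12 genes were lower in both berberine pairs with the former, and 1 was higher in both anti-DNP IgE pairs with the latter.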

Other observations

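The tests in this part, their predictions and the 2 lists of blood cell and epithelial genes were written after the data had been seen.

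Genes used by nearly all blood cells were lower with anti-DNP IgE, with medians of -0.11 (1.24th percentile) in DNP against control and -0.12 (1.45th) in BER+DNP against BER; 11 of the 21 measured genes lay below 0 in both pairs and 5 above, against 25.96% and 29.4% of all genes. With the filter at the 75th percentile, which left 10 of them, the median in DNP against control was 0.07, the opposite sign. Epithelial keratin and junction genes gave 0.02 and 0.03.

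Probe sets of many mast cell and blood cell genes were dim on all 4 arrays. The 2 brightest probe sets of a bright gene lay a median of 1.62 log2 apart, so that brightness is not a level of expression. A labelling that failed for the whole array is excluded by the poly-A control lys, whose 3' probe sets read at least 5.11 against a 75th percentile of 4.31, and a mispairing of the whole table by a rho of 0.203 between 2 probe sets of the same gene, where shuffling reached 0.032; a partial mispairing, insensitive single probe sets and the quality of the cells' own RNA remain open. RNA of another organism was predicted to leave under 60% of ribosomal protein genes among the brightest genes, and RNA of another mouse cell type at least 80%. The share was 61.4% (27 of 44 genes), or 27 of 45 with the paralog Rps4l, which the first version of the gene set had included; neither explanation could be told from the other. Whether the RNA came from the labelled line stays open, since ranks across different probe sets do not settle it.

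ATF4 targets were higher and DNA replication genes lower with berberine. A smooth trend with brightness does not account for the gap between the 2 list medians, since cyclic loess kept 108% of it. Little such trend was there to remove. Random lists matched on expression had medians of -0.008 for ATF4 targets and -0.002 for DNA replication genes in BER against control. In BER+DNP against DNP these were -0.034 and -0.023. Probe sets with the suffixes x and s do not account for the gap, since 88.8% remained without them. Cross-hybridisation of the other probe sets stays open, since probe sequences were not used. Noise of single arrays or cultures stays open, since its test is void: the gap of berberine (0.347) was reached in 1 of 3 splits of the arrays into pairs, its own, with 0.056 the highest of the others, but the 2 lists had been picked from 34 for their berberine values. That test replaced an earlier version with the same fault. RNA quality, which was not tested, also stays open, since the beta-actin control was lower by -0.57 at the 5' end and -0.31 at the 3' end in BER against control and by -0.59 and -0.22 in BER+DNP against DNP, while Gapdh was flat (0.05 and -0.03, then -0.08 and 0.02), and no biological explanation was tested.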
